A study of Mus musculus with 12 samples.

How the data were processed

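The 12 arrays were Agilent whole-genome mouse 4x44K arrays hybridised with Cy3-labelled RNA, 4 for each of wild-type normal, Apc normal and Apc polyp colorectal tissue, and samples were grouped by the genotype and tissue in their titles. Per the labels' protocols, total RNA was purified on silica columns with DNase digestion, and 0.1 ug of it was amplified and labelled with a low-input kit. The deposited scanner files hold spot intensity per the file headers: Agilent Feature Extraction 10.7.3.1 subtracted background and wrote a processed signal on a linear intensity scale, with no scaling between arrays recorded. The version is also in the submitters' processing notes. The deposited value table of the series holds a linear ratio or relative intensity whose making is not given in the sources used here. Set against the scanner values, about 99.5% of its entries per array lay within 1% of the processed signal divided by a constant, column medians were 0.9999 to 1, and no centring per gene was seen. Probe coordinates are those of mm9 in the scanner files.

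Control spots and 1403 outlier spots were left out, and log2 of the processed signal was averaged over the spots of a probe. The main values were these averages minus their 75th percentile over the probes of each array. Of 39429 probes, 27502 were named by RefSeq accession, 3549 by current symbol and 404 by synonym through a table of assembly GRCm38.p6, used for names only, and 7974 kept the file's name. This gave 30139 genes or transcripts. For a gene with several probes the probe with the highest mean over all 12 arrays was used, and 20082 genes whose probe was well above background on all 4 arrays of at least 1 group were tested. Over named genes, 1 of 29 other detected probes differed in sign by over 0.5 in the comparison of polyps with Apc normal tissue (Itgam).

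Each comparison used its own 8 arrays in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjusted p under 0.05 as the threshold and no fold minimum. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 38 lists, with an estimated correlation as an alternative. The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The lists held Wnt pathway targets, intestinal stem cell, cell cycle, ribosome biogenesis, nucleotide, carbon and lipid metabolism genes, and markers of epithelial, immune, stromal, nerve, fat, red blood and squamous cells, besides posterior Hox, inflammatory, immediate early, interferon and clock genes. Of their members, Ceacam1, Defa24, Defa5, Hbb-b1 and Hspa1b were not found under those names on the array, and Amd1 was tested as Amd2. A gene well above background on no array of 1 group has a bound only. The bound sets the bright group's mean against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal well above background (−6.60 to −5.17 on the log2 scale).

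The named genes were Apc, Myc, Axin2 and Lgr5, the 6 highest and 6 lowest log2 fold changes among called genes whose groups do not overlap and that were above background on all arrays of both groups, the 2 highest bounds per direction, and the 2 members of smallest p from each list. The last part took every list for polyps against Apc normal tissue and lists past the test otherwise. Genes with clone names were counted and not named. List members beyond these were named after their values were seen.

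Normal and polyp arrays of the same mouse number deviated together from their group means (r = 0.456, 0.170, 0.143 and 0.283 across genes for mice 103, 106, 107 and 110), while arrays of different mice gave −0.329 to 0.193. The highest of these, normal 106 with polyp 110, lay above the same-mouse values of mice 106 and 107, so the pairing rests mainly on the numbers in the titles. Slide 1 held all wild-type arrays, slide 2 mice 103 and 106, and slide 3 mice 107 and 110. Each slide is also a scan. A random block for slide, in a fit of all 12 arrays, had a correlation of −0.0816.

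The alternatives were the median of each array, quantile normalization, normexp correction (offset 50) with quantile normalization, the value table, no filter or a stricter filter on dim probes, the mean over a gene's probes, all 12 arrays in 1 fit, a variance trend with robust eBayes, array weights, slide as a random block, a 2-fold minimum, each array left out in turn and, for polyps against Apc normal tissue, the mouse number or the slide as a block and each slide alone. Alternatives chosen after seeing the data left out both arrays of mouse 107 and the Apc normal arrays of mice 106 and 110. The steps were tested on simulated data with the real means and spreads of the 20082 genes. For polyps against Apc normal tissue, 4%, 66%, 74% and 92% of 50 genes each changed by 0.5, 1, 2 and 3 on the log2 scale were recovered, for Apc normal against wild-type tissue 8%, 58%, 74% and 86%, and for polyps against wild-type tissue 20%, 70%, 88% and 90%. Of 19882 unchanged genes 5, 7 and 9 were called. The simulated genes varied independently of each other, and far fewer changed than in the real polyp comparisons. These rates need not carry over to the real data.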

Results

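Gene expression was measured in colorectal tissue of mice heterozygous for the Apc Δ716 allele, a truncating allele of the tumour suppressor that limits Wnt signalling, and of wild-type C57BL/6N mice. The 12 single-colour arrays fell into 3 groups of 4: normal tissue of wild-type mice, normal tissue of Apc mutant mice, and polyps of Apc mutant mice. Mice were female and 14 weeks old, and each polyp array shared its mouse number (103, 106, 107 or 110) with an Apc normal array. Between 64.6% and 73.8% of the spots of an array were well above background, no spot was saturated, and 20082 of 30139 genes or transcripts were tested. The number of arrays limits the precision of what follows. Levels are log2 signals relative to the 75th percentile of the array, given as mean ± SD (n = 4), and differences are log2 fold changes ± SE between 4 and 4 arrays. Within a group, arrays correlated at r = 0.959 to 0.992 across genes, which are not independent replicates. The first principal component held 66.3% of the variance and placed polyps at 106 to 137 and normal tissue at −76.5 to −25.2.

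The first comparison set polyps against normal tissue of the same Apc mutant mice. Targets of the Wnt pathway, cell cycle genes, Paneth cell and small intestine genes and inflammatory mediators were higher in polyps. Genes of absorptive colonocytes, enteroendocrine cells, mitochondrial metabolism and smooth muscle were lower. Of these lists only that of the cell cycle held with an estimated correlation between genes. Myc, a growth-promoting transcription factor, rose 3.51-fold, from −1.66 ± 0.13 to 0.15 ± 0.18 (1.81 ± 0.12, limma adjusted p = 6.17e-05). Axin2, a feedback inhibitor of Wnt signalling, rose 7.04-fold (2.82 ± 0.31, adjusted p = 0.000318), and Lgr5, a receptor that marks intestinal stem cells, rose 8.75-fold (3.13 ± 0.16, adjusted p = 2.58e-05). The chloride-bicarbonate exchanger Slc26a3 fell 39.6-fold (−5.31 ± 0.42) and the water channel Aqp8 fell 30.6-fold (−4.94 ± 0.47), with limma adjusted p = 9.21e-05 and 0.000169.

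**Figure D1:**
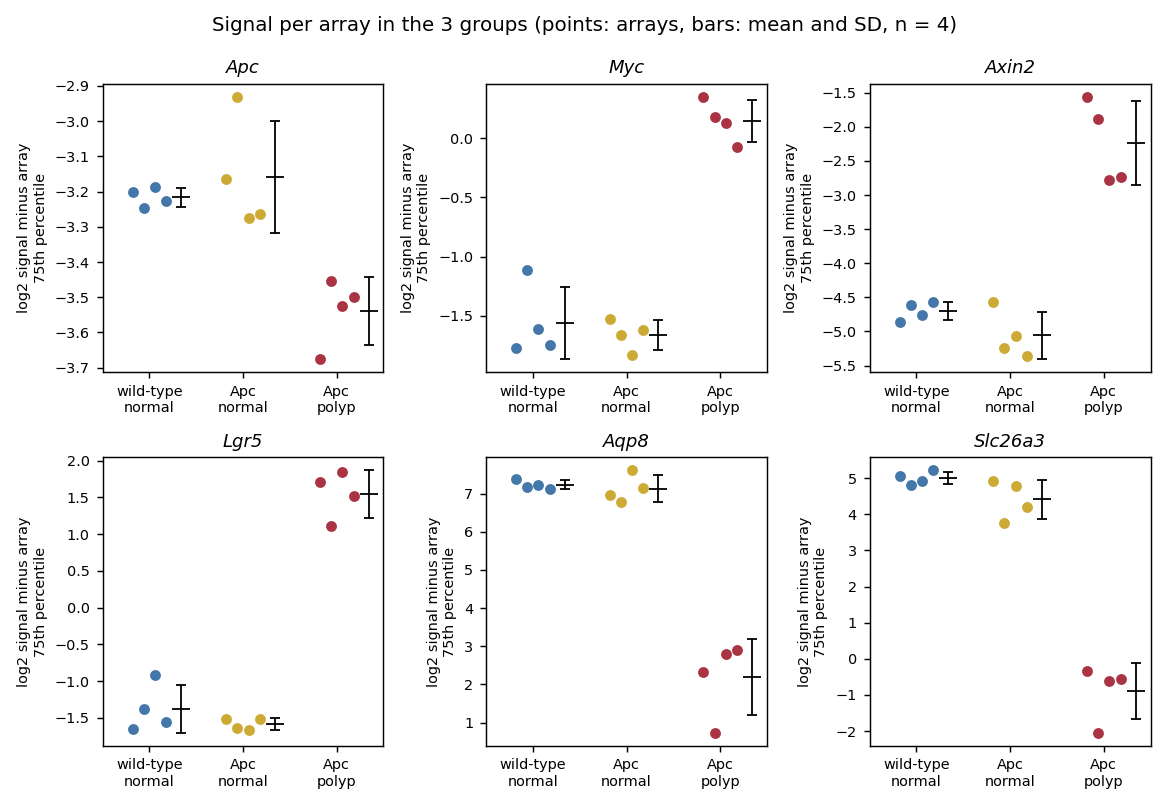
Signal of Apc, Myc, Axin2, Lgr5, Aqp8 and Slc26a3 on each array, as log2 signal minus the 75th percentile of the array, in wild-type normal, Apc normal and Apc polyp tissue; points are arrays and bars are mean and SD (n = 4). The 4 polyp arrays lie above all 8 normal arrays for Myc, Axin2 and Lgr5 and below all 8 for Apc, Aqp8 and Slc26a3.

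The mutated gene itself, Apc, read on chromosome 18 by a probe at 34432157 to 34436232 (mm9), stood at −3.22 ± 0.03 in wild-type normal, −3.16 ± 0.16 in Apc normal and −3.54 ± 0.10 in polyp tissue. It was 1.30-fold lower in polyps than in Apc normal tissue (−0.38 ± 0.11, limma adjusted p = 0.0265). That call ended without the Apc normal array of mouse 103 (adjusted p = 0.0510) or 106 (0.0516) or the polyp array of mouse 103 (0.0712), 107 (0.0571) or 110 (0.0531), and adjusted p ranged from 0.00599 to 0.356 over 25 alternatives. Where the probe lies relative to the altered part of the allele is not given in the sources used here, so its level is no check of the genotype labels.

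Among genes measured on every array of both groups, the highest rises were those of Mmp10 (182-fold, 7.51 ± 0.42) and Mmp13 (127-fold, 6.99 ± 0.28), secreted metalloproteinases, and of Cfi, complement factor I (174-fold, 7.44 ± 0.33). The alpha-defensins Defa36, Defa32 and Defa3, antimicrobial peptides of Paneth cells, rose 180-fold, 140-fold and 137-fold. Defensin genes are near-identical copies, and their single values are uncertain. They also leaned on single arrays: without the Apc normal array of mouse 106 or 107, the log2 differences were 8.41 and 6.74 for Defa36, 8.03 and 6.36 for Defa32, and 7.96 and 6.28 for Defa3. The osteopontin gene Spp1 was not well above background on any Apc normal array and was at least 120.5-fold higher in polyps (adjusted p = 8.69e-06), and the chemokine gene Cxcl3 was at least 63.4-fold higher (adjusted p = 2.65e-05). The strongest falls were those of the cytochrome P450 Cyp2c55 (99.1-fold, −6.63 ± 0.91), Slc26a3, the butyrophilin-like gene Btnl1 (33.0-fold, −5.05 ± 1.04), Aqp8, the muscle intermediate filament gene Des (27.7-fold, −4.79 ± 0.49) and Synpo2 (23.3-fold, −4.54 ± 0.53). Without the Apc normal array of mouse 107, Cyp2c55 stood at −5.83 and Btnl1 at −4.21 (−5.66 without that of mouse 110), and Cyp2c55 at −6.03 without the polyp array of mouse 106. For Synpo2 this was the brightest of 3 probes, and the other 2 read −1.79 and −2.02. Syce3 and Cyp2c54 were not well above background on any polyp array and were at least 15.6-fold and at least 13.7-fold lower there.

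Across all genes, 9129 passed the test, 4121 higher and 5008 lower in polyps (limma, Benjamini-Hochberg), and 1827 rose and 2375 fell by 2-fold or more. Which direction held more genes depended on the scaling: after quantile normalization 4675 were higher and 4369 lower, and after normexp correction 4696 and 4268, with 102 and 101 of the 9129 genes at the opposite sign. By measured signal, a rise above 32-fold was seen for 99 genes and a fall of that size for 12. These counts and those of 2-fold changes include genes with a bound only, whose bound can be lower. Examples are Il23a (5.505) and Cyp2c54 (−5.148), both with a bound under 32-fold. Slides 2 and 3 each held 2 mice with both tissues. With mouse number as a block 9321 genes passed and with slide as a fixed block 8915, and within slide 2 and slide 3 alone 3466 and 1902 passed, from 2 arrays per tissue. On both slides the normal samples lay at positions 1 and 3 and the polyps at positions 2 and 4. The same positions compared on the wild-type slide gave 0 genes past the limma test and 966 of 20082 at an unadjusted p under 0.05. With 2 arrays against 2, that test cannot exclude an effect of position.

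Of 38 gene lists, 11 stood higher and 11 lower in polyps by a test with a preset correlation between genes. Only the cell cycle list held with an estimated correlation. Its estimate, 0.0142, was near the preset 0.01, yet its adjusted p in the list test went from 6.37e-10 to 0.0254. The alternative was thus stricter for more than the correlation, and a list that failed it is left undecided. Of the 35 splits of these 8 arrays, 4, the real one included, put 22 or more lists past the preset test, with 25 in the highest other split. The counts of single genes per list are therefore given with each list.

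All 19 tested cell cycle genes rose (list adjusted p = 6.37e-10, and adjusted p = 0.0254 with an estimated correlation), a count that was also 19 adjusted over the list alone. Among them were the mitotic kinase Bub1 (4.43-fold, 2.15 ± 0.15) and the topoisomerase Top2a (3.64-fold, 1.87 ± 0.13). Of 20 Wnt pathway targets 19 rose and 0 fell, over all genes and adjusted over the list alone (list adjusted p = 2.66e-10, and adjusted p = 0.246 with an estimated correlation). The secreted Wnt inhibitor Wif1 rose 40.7-fold (5.35 ± 0.34), the transcription factor gene Sp5 by 5.66 ± 0.40 and Prox1 by 5.28 ± 0.50. Ephb2 was the member that did not pass (−0.17 ± 0.17). Of 12 stem cell markers, 6 of them also on the Wnt list, 8 rose and 2 fell (8 and 2 adjusted over the list alone), with list adjusted p = 0.00637, and adjusted p = 0.273 with an estimated correlation. The Wnt-target receptor Tnfrsf19 rose by 3.35 ± 0.22 (1.55 on a second probe), while Msi1, an RNA-binding protein gene, fell by 1.85 and Rgmb, a BMP co-receptor gene, fell by 0.99.

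**Figure D2:**
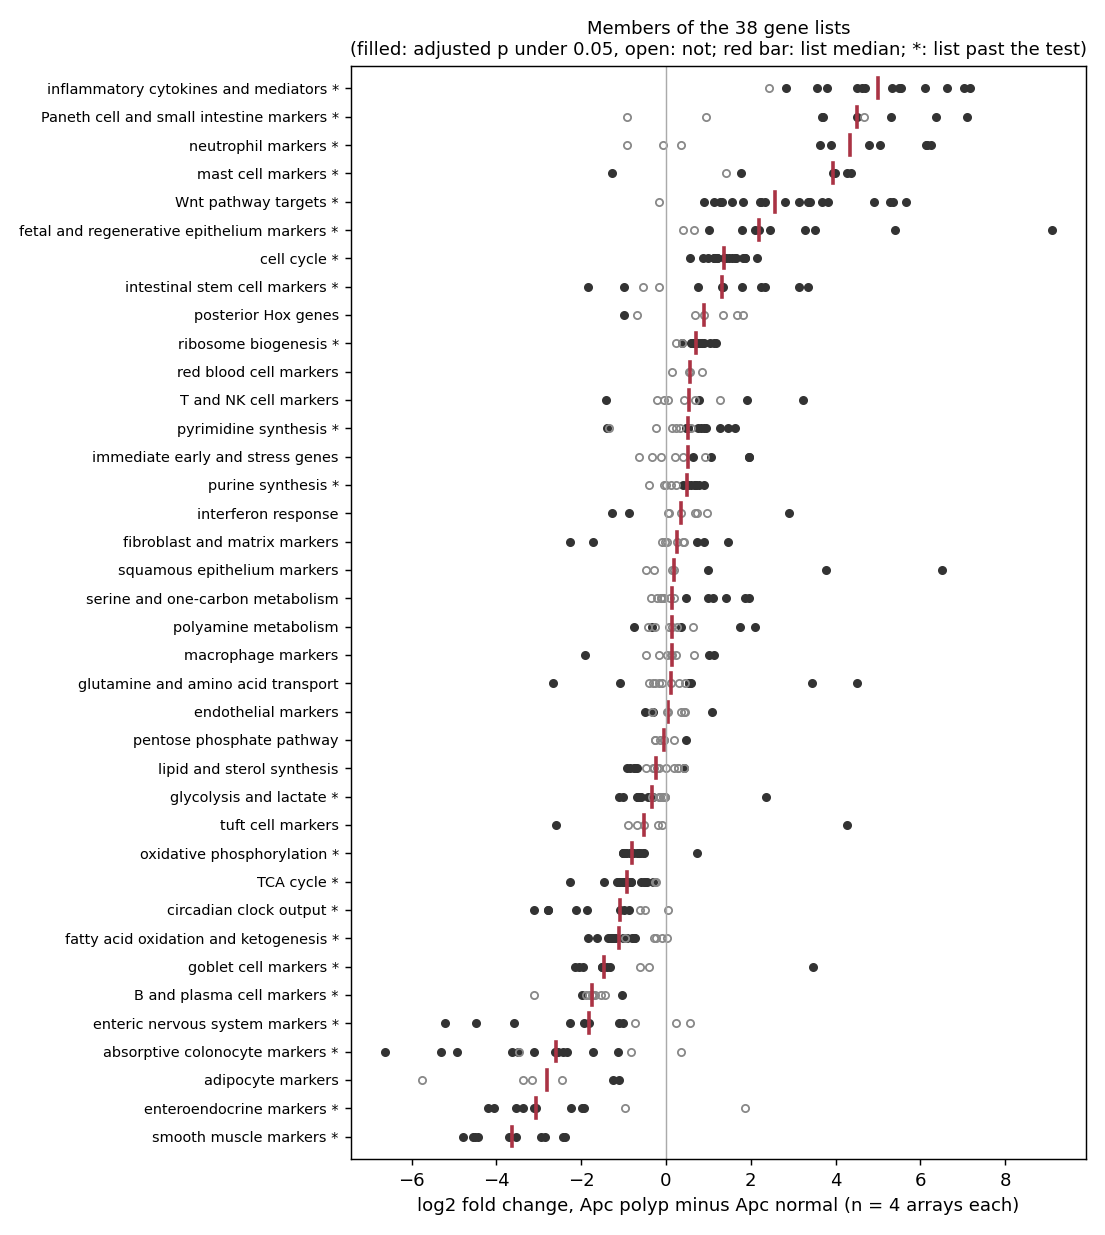
Log2 fold change of each tested member of the 38 gene lists, Apc polyp minus Apc normal (n = 4 arrays each), with lists ordered by their median; filled points passed the test over all genes, open points did not, red bars are medians and an asterisk marks lists past the preset-correlation test. Medians run from −3.62 for smooth muscle to 5.01 for inflammatory mediators, and all 19 cell cycle points lie above 0.

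Genes of ribosome biogenesis and of pyrimidine and purine synthesis were higher in polyps by smaller amounts. Of 20 ribosome biogenesis genes 18 rose and 0 fell, among them the RNA polymerase I subunit Polr1a (0.85 ± 0.11) and Mybbp1a (1.13 ± 0.15). In pyrimidine synthesis 10 of 17 rose, led by the ribonucleotide reductase gene Rrm1 (1.27 ± 0.11), and the kinase gene Cmpk1 fell by 1.39. In purine synthesis 9 of 14 rose and 0 fell, among them Paics (0.90 ± 0.10) and Gart (0.68 ± 0.10). Adjusted over the list alone the counts were 18 and 0, 11 and 2, and 9 and 0. These 3 lists passed the preset test (adjusted p = 4.98e-07, 0.00274 and 0.00252), with adjusted p = 0.334, 0.334 and 0.273 with an estimated correlation. Serine and one-carbon metabolism did not pass as a list (adjusted p = 0.0826), though 6 of its 14 genes rose, also adjusted over the list alone, and it passed without the Apc normal array of mouse 107 (0.0457, with a range of 0.0192 to 0.334 over its alternatives). They included Shmt2 (1.42 ± 0.18), Psat1 (1.87 ± 0.25) and Phgdh (1.97 ± 0.28), enzymes of serine synthesis and use.

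Genes of mitochondrial energy metabolism were lower in polyps. Of 20 TCA cycle genes 18 fell, such as Suclg1 (−1.11 ± 0.11) and the citrate synthase gene Cs (−1.16 ± 0.13). Of 22 oxidative phosphorylation genes 21 fell, with a median difference of −0.80, while Ndufa4, a cytochrome oxidase-associated subunit gene, rose by 0.73 ± 0.22. In fatty acid oxidation and ketogenesis 15 of 20 fell and 0 rose, among them the enoyl-CoA hydratase gene Echs1 (−1.20 ± 0.12) and the carnitine carrier gene Slc25a20 (−1.84 ± 0.19). Adjusted over the list alone these counts were the same. The lists passed at adjusted p = 3.08e-07, 3.08e-07 and 1.07e-05, with adjusted p = 0.320, 0.334 and 0.320 with an estimated correlation. On the same arrays smooth muscle markers had a median difference of −3.62 and absorptive colonocyte markers one of −2.60. Of 18 genes of glycolysis and lactate, 9 fell and 1 rose, also adjusted over the list alone. The phosphofructokinase gene Pfkp fell by 1.10 (−0.37 on a second probe) and Aldoa by 0.69, while Slc16a3, a lactate exporter gene, rose by 2.36 ± 0.31. The glycolysis list passed at adjusted p = 0.0288 (adjusted p = 0.492 with an estimated correlation). It did not pass after quantile normalization (median −0.03, adjusted p = 0.609), after normexp correction (−0.07, 0.507) or without the Apc normal array of mouse 110 (0.0677), and its adjusted p ranged from 0.0154 to 0.609 over its alternatives.

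Markers of differentiated epithelial cells moved apart. Of 16 absorptive colonocyte markers 13 fell and 0 rose (adjusted p = 1.07e-05, and adjusted p = 0.320 with an estimated correlation), with the mucin gene Muc3 at −2.55 ± 0.23. Of 11 goblet cell markers 8 fell, such as Clca1 (−1.96 ± 0.22) and Fcgbp (−2.06 ± 0.24), and Ang4, an antimicrobial ribonuclease also made by Paneth cells, rose by 3.47 ± 0.64 (list adjusted p = 0.00731, and adjusted p = 0.492 with an estimated correlation). A second Clca1 probe read −0.16. Of 11 enteroendocrine markers 9 fell and 0 rose (list adjusted p = 0.000253, and adjusted p = 0.273 with an estimated correlation), with the granule proteins Chga and Chgb at −3.36 ± 0.23 and −3.12 ± 0.23. Of 9 Paneth cell and small intestine markers 6 rose and 0 fell, or 6 and 1 adjusted over the list alone (list adjusted p = 0.000369, and adjusted p = 0.273 with an estimated correlation). The lectin gene Itln1 rose 39.5-fold (5.30 ± 0.20) and the matrilysin gene Mmp7, on chromosome 9 at 7697641 to 7697700 (mm9), rose 82.7-fold (6.37 ± 0.32). Of 11 fetal and regenerative epithelium markers 9 rose and 0 fell (list adjusted p = 1.07e-05, and adjusted p = 0.268 with an estimated correlation), among them Spp1. Counts for the colonocyte, goblet, enteroendocrine and fetal lists were the same adjusted over the list alone.

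Inflammatory mediators and markers of neutrophils and mast cells were higher, and B and plasma cell markers were lower. Of 14 inflammatory cytokines and mediators 13 rose, or 14 adjusted over the list alone, with a median of 5.01, or 4.65 with 3 members at their bound (adjusted p = 1.63e-08, and adjusted p = 0.297 with an estimated correlation). Il11, a cytokine of the interleukin-6 family, rose by 6.63 ± 0.39, and Il23a was at least 24.0-fold higher. Of 10 neutrophil markers 7 rose and 0 fell, or 8 and 0 adjusted over the list alone, with a median of 4.34, or 3.92 with 2 members at their bound (list adjusted p = 0.000698, and adjusted p = 0.320 with an estimated correlation). Mmp9 rose by 4.79 ± 0.32, and the chemokine receptor gene Cxcr2 was at least 12.1-fold higher. Of 7 mast cell markers 5 rose and the receptor gene Kit, which interstitial cells of Cajal also express, fell by 1.27, with the same counts adjusted over the list alone (list adjusted p = 0.00912, and adjusted p = 0.334 with an estimated correlation). Cpa3 and Mcpt2, mast cell proteases, rose by 4.27 ± 0.51 and 4.37 ± 0.54. B and plasma cell markers had 2 of 10 members lower, also adjusted over the list alone, Pax5 (−1.98 ± 0.33) and Cd22 (−1.04 ± 0.29). That list passed at adjusted p = 0.0440 (adjusted p = 0.536 with an estimated correlation), and its score was higher in the Apc normal arrays of mice 106 and 110 than in the other Apc normal arrays. It did not pass without the Apc normal array of mouse 106 (0.107) or 110 (0.0827) or the polyp array of mouse 103 (0.0771) or 106 (0.0905), with a range of 0.000749 to 0.536 over its alternatives. The Cd22 call ended without the polyp array of mouse 106 (adjusted p = 0.0525, with a range of 0.00461 to 0.187 over its alternatives).

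Genes of the deeper wall were lower, and so were circadian clock output genes. All 10 smooth muscle markers fell, also adjusted over the list alone, with a median of −3.62, or −3.23 with 1 member at its bound (list adjusted p = 4.98e-07, and adjusted p = 0.297 with an estimated correlation). Smtn was at −2.44 ± 0.16 (−1.25 on a second probe) and Actg2 at −3.53 ± 0.27. Of 11 enteric nervous system markers 8 fell, or 9 adjusted over the list alone (list adjusted p = 0.00392, and adjusted p = 0.334 with an estimated correlation). Of 11 circadian clock output genes 8 fell, or 9 adjusted over the list alone (list adjusted p = 0.000369, and adjusted p = 0.320 with an estimated correlation), such as Per2 (−2.12 ± 0.17) and Dbp (−3.11 ± 0.31).

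The other 15 lists did not pass. Median differences were −0.06 for the pentose phosphate pathway, whose test leaned upward (adjusted p = 0.992), 0.12 for glutamine and amino acid transport (0.436), 0.14 for polyamine metabolism (0.343) and −0.24 for lipid and sterol synthesis (0.390). Single members still passed, such as the cystine transporter gene Slc7a11 (4.52 ± 0.61), the glutaminase gene Gls2 (3.45 ± 0.32) and the polyamine gene Mtap (2.10 ± 0.18). Medians were −0.52 for tuft cells (0.597), 0.13 for macrophages (0.75), 0.56 for T and NK cells (0.390), 0.27 for fibroblasts and matrix (0.496) and 0.05 for endothelium (0.589). The granzyme gene Gzmb rose by 3.23 ± 0.69, the matrix genes Lum and Postn fell by 2.26 and 1.72, and the tuft-cell gene Avil rose by 4.27 ± 0.40. The integrin gene Itgam fell by 1.91 on the probe used and stood at 1.29 on another probe. Medians were −2.81 for adipocytes (adjusted p = 0.0826), 0.56 for red blood cells (0.325), 0.19 for squamous epithelium (0.128), 0.90 for posterior Hox genes (0.755), though −0.20 without the Apc normal array of mouse 107, 0.52 for immediate early genes (0.0697) and 0.37 for the interferon response (0.572). The keratin gene Krt14 rose by 3.78 ± 0.32. Rises and falls were 5 and 2 of 15 for glutamine and amino acid transport, 3 and 2 of 11 for polyamines, 1 and 5 of 16 for lipids and sterols, 3 and 1 of 10 for T and NK cells, 3 and 2 of 11 for fibroblasts, 4 and 0 of 10 for immediate early genes, 3 and 0 of 7 for squamous epithelium, 1 and 1 of 7 for tuft cells, 1 and 0 of 7 for pentose phosphate and 0 and 0 of 4 for red blood cells, all the same adjusted over the list alone. They were 2 and 1 of 10 for macrophages, 1 and 2 of 9 for endothelium, 1 and 2 of 9 for interferon, 0 and 2 of 6 for adipocytes and 0 and 1 of 7 for posterior Hox genes. For these 5 lists the counts adjusted over the list alone were 0 and 1, 1 and 0, 1 and 0, 0 and 3, and 0 and 0. With mouse number as a block the adipocyte list passed (adjusted p = 0.0279), as did Alas2 (0.0283) and Hoxa11 (0.00737), and the interferon-induced gene Oas1a, past in the unblocked test (0.0343), did not (0.0647). Over their alternatives these adjusted p ranged from 0.0113 to 0.569, 0.0122 to 0.516, 0.00737 to 0.758 and 0.0118 to 0.289. The adipocyte list also passed without the Apc normal array of mouse 103 (0.0113) or the polyp array of mouse 110 (0.0381), and the immediate early list without the Apc normal array of mouse 103 (0.0412) or 107 (0.0431) or the polyp array of mouse 107 (0.0204).

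The second comparison set normal tissue of Apc mutant mice against normal tissue of wild-type mice. Mmp7 was 45.3-fold higher in Apc normal tissue (5.50 ± 0.38, limma adjusted p = 0.00476), at −0.22 ± 0.62 against −5.72 ± 0.59. Only 2 wild-type arrays had Mmp7 well above background, so the size of this fold rests on a level near background. Red cell genes were higher as well, with the haemoglobin gene Hbb-bt up 6.31-fold (2.66 ± 0.27, adjusted p = 0.0271) and Alas2, which starts haem synthesis in red cell precursors, up 5.63-fold (2.49 ± 0.23, adjusted p = 0.0221). The Wnt-pathway genes Wif1 (5.47-fold, 2.45 ± 0.32, adjusted p = 0.0402) and Sp5 (at least 2.08-fold, adjusted p = 0.0344) were higher. Apc, Myc, Axin2 and Lgr5 differed by 0.06 ± 0.11, −0.10 ± 0.16, −0.36 ± 0.18 and −0.21 ± 0.17 and did not pass (adjusted p = 0.819, 0.788, 0.348 and 0.556).

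**Figure D3:**
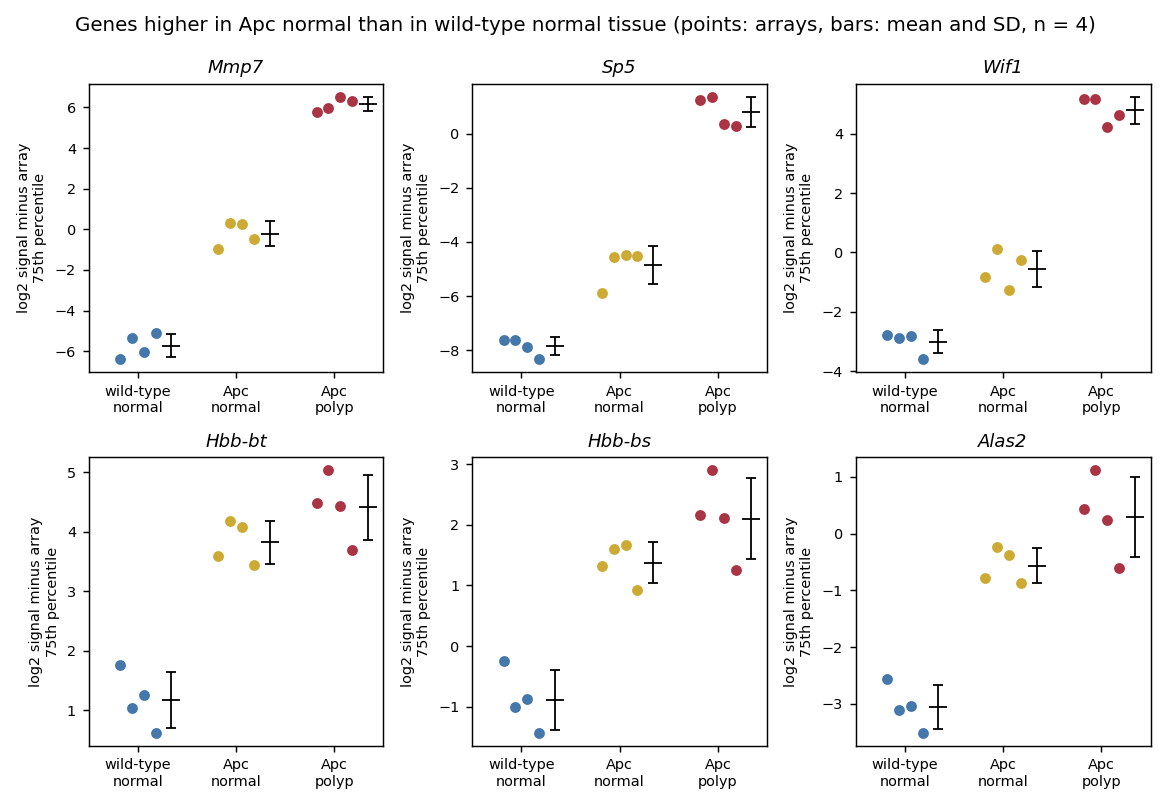
Signal of Mmp7, Sp5, Wif1, Hbb-bt, Hbb-bs and Alas2 on each array, as log2 signal minus the 75th percentile of the array, in the 3 tissue groups; points are arrays and bars are mean and SD (n = 4). Apc normal arrays lie above all wild-type arrays, with Mmp7 at −0.22 against −5.72 and Hbb-bt at 3.83 against 1.17. Sp5 was not well above background on any wild-type array, and Mmp7 was so on only 2 of them.

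In all, 34 of 20082 genes passed, 30 higher and 4 lower, and 3439 of 20082 had an unadjusted p under 0.05. Some genes not named above were above background on all arrays of both groups, which Mmp7 and Sp5 were not. The highest differences among these were those of the interferon-induced chemokine gene Cxcl9 (6.86-fold, limma adjusted p = 0.0468), Hbb-bs (4.83-fold, 0.0344) and the neutrophil antigen gene Cd177 (4.16-fold, 0.0344). The epithelial envelope gene Sprr2e was at least 1.92-fold higher (adjusted p = 0.00153). The 4 lower genes were Tcp11 (2.41-fold, −1.27 ± 0.15), Trank1 (1.91-fold, −0.93 ± 0.11), Slc22a13b (1.85-fold, −0.89 ± 0.12) and Ttll3 (1.85-fold, −0.88 ± 0.11).

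Of the 38 lists, 13 stood higher and 2 lower in Apc normal tissue by the preset test, and 0 with an estimated correlation. Of 4 red blood cell markers 2 passed over all genes and 4 adjusted over the list alone, with a median of 2.17 (list adjusted p = 7.79e-07, and adjusted p = 0.317 with an estimated correlation). Of 9 Paneth cell and small intestine markers 1 passed over all genes, Mmp7, and 6 adjusted over the list alone, with a median of 2.08 (list adjusted p = 2.82e-05, and adjusted p = 0.317 with an estimated correlation). Reg3g, an antimicrobial lectin gene, differed by 5.24 ± 1.51 and Pla2g2a by 2.08 ± 0.48, not past over all genes. Mast cell markers had a median of 1.45, with Mcpt4 at 2.42 ± 0.40 (adjusted p = 0.0642) and Mcpt1 at 2.59 ± 0.49 (0.0783), and 4 of 7 members passed adjusted over the list alone (list adjusted p = 0.00294, and adjusted p = 0.397 with an estimated correlation). Medians of the immune lists were 1.0 for neutrophils (0.81 with 1 member at its bound), 0.97 for B and plasma cells, 0.83 for T and NK cells, 0.58 for inflammatory mediators, 0.50 for the interferon response and 0.35 for macrophages. The rises of all of these lists but the interferon response lay mainly in 2 of the 4 Apc normal arrays. The B and plasma cell score was 0.80 and 1.01 in mice 106 and 110, against −1.06 and −1.53 in mice 103 and 107 and a wild-type mean of −1.16. For T and NK cells the scores were −0.91 and −0.74 against −1.90 and −1.91 (wild-type −2.17), and for inflammatory mediators −3.30 and −3.61 against −4.74 and −5.01 (−4.87). Macrophage scores were 2.45 and 2.11 against 1.63 and 1.30 (1.53), and neutrophil scores −1.24 and −1.58 against −2.85 and −2.43 (−3.01). No member of these 6 lists passed over all genes. Adjusted over the list alone, 4 neutrophil markers were higher and 1 lower, 6 T and NK cell markers and 2 interferon genes were higher, and 0 members of the others passed. These 6 lists passed at adjusted p = 0.00101 to 0.0489, with adjusted p = 0.511 to 0.694 with an estimated correlation. Smooth muscle markers had a median difference of −0.46 (list adjusted p = 0.000295), with 0 of 10 past over all genes and 4 adjusted over the list alone. The enteric nervous system list had a median of −0.58 (0.00656) with 0 members past in either count, and both had adjusted p = 0.692 with an estimated correlation. Lipid and sterol synthesis (median 0.46), serine and one-carbon metabolism (0.23), ribosome biogenesis (0.18) and glycolysis and lactate (0.16) passed upward at adjusted p = 0.00509 to 0.0236 with 0 members past in either count (adjusted p = 0.511 to 0.694 with an estimated correlation).

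Lists that did not pass here included the Wnt pathway targets (median 0.00, mean 0.31, adjusted p = 0.302), with Sp5 and Wif1 past, the cell cycle (0.11, 0.342), stem cell markers (−0.14, 0.342), the TCA cycle (−0.05, 0.451), oxidative phosphorylation (0.03, 0.537) and absorptive colonocytes (−0.24, 0.222). The goblet cell list had a median of −0.08 and a mean of 0.39 with an upward test (0.535). For glutamine and amino acid transport the median was −0.07 and the test downward, against a mean of 0.06 (0.695). Of the other 15 lists, at adjusted p = 0.138 to 0.841, posterior Hox genes had the median farthest from 0, −1.02 (0.302), and it was −0.07 without the Apc normal array of mouse 107.

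The count of 34 was fragile: it was 530 (330 higher and 200 lower) without the Apc normal array of mouse 103, 2 without that of mouse 106 or 110, 31 without that of mouse 107 (13 of them among the 34), and 9, 2, 2 and 11 without the wild-type array of mouse 102, 104, 105 and 108. It was 3 (3 higher and 0 lower) after normexp correction, 2 without the filter on dim probes, and 0 without both Apc normal arrays of high B cell markers (mice 106 and 110), an alternative chosen after seeing the data. Mmp7 and Sprr2e passed without any single array (adjusted p = 0.00359 to 0.0450 and 0.00237 to 0.0203), but not without both of those Apc normal arrays (0.151 and 0.0561), and no other gene passed without the wild-type array of mouse 104. Over their alternatives their adjusted p ranged from 3.96e-05 to 0.151 and from 0.00104 to 0.0751. The wild-type arrays shared a slide that held no other group. A fit of all 12 arrays gave 226 genes, and 814 with slide as a random block, 467 higher and 347 lower. The block correlation was negative (−0.0816), which makes the error between slides smaller, so the count of 814 is no allowance for slide.

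Of the 15 list calls of this comparison, 7 ended without 1 of the arrays. The B and plasma cell list did not pass without the Apc normal array of mouse 106 (0.0524) or 110 (0.0651), nor did the inflammatory list (0.133 and 0.0642, and 0.0871 without the wild-type array of mouse 108). Ribosome biogenesis did not pass without the wild-type array of mouse 102 (0.0562) or 108 (0.0871) or the Apc normal array of mouse 106 (0.329) or 110 (0.0760), nor macrophages without the wild-type array of mouse 102 (0.0502) or 108 (0.252) or the Apc normal array of mouse 103 (0.0528), 106 (0.318) or 110 (0.151). The enteric nervous system list did not pass without the Apc normal array of mouse 103 (0.0755), glycolysis and lactate without that of mouse 110 (0.0651), and serine and one-carbon metabolism without that of mouse 110 (0.0651) or the wild-type array of mouse 102 (0.0562). Neutrophils (0.0552) and the interferon response (0.0725) did not pass with slide as a random block. Over their alternatives adjusted p ranged from 0.000314 to 0.865 for B and plasma cells, 0.000264 to 0.692 for inflammatory mediators, 0.00344 to 0.920 for ribosome biogenesis, 0.00175 to 0.870 for macrophages, 0.000264 to 0.692 for the enteric nervous system, 0.00137 to 0.692 for glycolysis, 0.0112 to 0.511 for serine, 0.00432 to 0.692 for neutrophils and 0.000314 to 0.511 for interferon. Other lists passed with an array left out. Without the Apc normal array of mouse 107 absorptive colonocytes passed downward (median −0.36, adjusted p = 0.00257), as did fatty acid oxidation (−0.23, 0.0067), and fetal markers passed upward (0.33, 0.0330). The circadian list passed downward without the wild-type array of mouse 105 (−0.43, 0.0153), fibroblasts downward without that of mouse 108 (−0.40, 0.0183), and adipocytes upward without the Apc normal array of mouse 103 (1.08, 0.0388). Over their alternatives adjusted p ranged from 0.00257 to 0.735, 0.0067 to 0.865, 0.0330 to 0.889, 0.0153 to 0.694, 0.0183 to 0.954 and 0.0388 to 0.882 for these 6 lists. Lists past the test numbered 9 without the Apc normal array of mouse 110 and 6 without both arrays, and 6 of the 35 splits of the 8 arrays gave 15 or more lists, with 19 in the highest other.

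The third comparison set polyps against normal tissue of wild-type mice. The antimicrobial lectin gene Reg3g was 855-fold higher in polyps (9.74 ± 0.50, limma adjusted p = 5.18e-06), and the calprotectin genes S100a8 and S100a9, abundant in neutrophils, were 624-fold and 406-fold higher (9.28 ± 0.63 and 8.67 ± 0.59). Mmp7 was 3748-fold higher (11.87 ± 0.30, limma adjusted p = 2.95e-07). It was well above background on only 2 of 4 wild-type arrays, so this fold rests on a level near background. Cyp2c55 was 117-fold lower (−6.87 ± 0.60, adjusted p = 4.10e-05, and −6.26 without the polyp array of mouse 106) and Mptx1, a mucosal pentraxin gene, 92.0-fold lower (−6.52 ± 0.31, adjusted p = 3.80e-06). Myc, Axin2 and Lgr5 were 3.27-fold, 5.50-fold and 7.57-fold higher, and Apc was 1.25-fold lower (−0.32 ± 0.08, adjusted p = 0.00741).

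Mmp10 (520-fold), the acute-phase gene Saa3 (355-fold) and the arginase gene Arg1 (228-fold) were also among the highest (Saa3 9.11 on the log2 scale without the polyp array of mouse 103), and Defa36 and Defa21, not well above background in wild-type tissue, were at least 2703-fold and at least 507-fold higher. Among the lowest were Slc26a3 (59.5-fold), Btnl1 (55.1-fold), Slc37a2 (46.7-fold) and the sulfotransferase gene Sult1a1 (43.8-fold), and Slc30a10 and Syce3 were at least 67.2-fold and at least 29.4-fold lower. In total 12096 genes passed, 5508 higher and 6588 lower, with 160 above 32-fold higher and 42 above 32-fold lower. After quantile normalization 6048 were higher and 5896 lower, and after normexp correction 6020 and 5882, with 191 and 200 of the 12096 genes at the opposite sign.

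Of the 38 lists, 13 were higher and 9 lower by the preset test, and 0 held with an estimated correlation (adjusted p = 3.73e-09 to 0.0450 by the preset test, and adjusted p = 0.275 to 0.630 with an estimated correlation). All 19 cell cycle genes, 19 of 20 Wnt targets, 19 of 20 ribosome biogenesis genes, all 14 inflammatory mediators and all 4 red blood cell markers rose, with the same counts adjusted over the list alone. Rises and falls over all genes were 8 and 3 of 12 stem cell markers, 12 and 3 of 17 pyrimidine genes and 12 and 0 of 14 purine genes. They were 7 and 1 of 14 serine and one-carbon genes and 7 and 0 of 9 Paneth cell and small intestine markers. For fetal markers they were 10 and 0 of 11, for neutrophil markers 8 and 2 of 10, and for mast cell markers 6 and 1 of 7. These were the same adjusted over the list alone. The 2 lower neutrophil markers were Csf3r (−0.47) and Ly6g (−1.41), and the lower mast cell marker was Kit (−1.50). Sp5 was at least 104.6-fold higher and Mcpt4 82.6-fold higher.

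Of the lists that stood lower, all 10 smooth muscle markers, 19 of 20 TCA cycle genes, 20 of 22 oxidative phosphorylation genes and 16 of 20 fatty acid oxidation genes fell. The TCA count was 20 adjusted over the list alone, and Ndufa4 rose (0.95). For absorptive colonocytes 13 of 16 fell and Guca2b, a gut peptide gene, rose (0.56). For enteroendocrine cells 9 of 11 fell and Nts, the neurotensin gene, rose (3.72). For goblet cells 8 of 11 fell, for the enteric nervous system 9 of 11 (9 lower and 1 higher adjusted over the list alone), and for the circadian clock output 8 of 11, or 9 adjusted over the list alone. The goblet list, past at 0.0450, did not pass after quantile normalization (0.0801) or without the wild-type array of mouse 104 (0.0720) or 108 (0.0843). Glycolysis and lactate did not pass (adjusted p = 0.355), nor did B and plasma cells (0.287), T and NK cells (0.0576, and 0.00546 without the polyp array of mouse 103) or adipocytes (0.208). The fibroblast list had a median of 0.00, a mean of −0.09 and an upward test (0.814), and the tuft cell list a median of −0.22, a mean of 0.09 and a downward test (0.914). Polyps and wild-type tissue shared no slide. Polyps and Apc normal tissue, which shared slides 2 and 3, differed at 8915 genes with slide as a fixed block, and Apc normal and wild-type tissue, on different slides, at 34 (0 to 814 over the alternatives). For lists, 6 of the 35 splits gave 22 or more lists, with 23 in the highest other.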

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

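The tests of polyp tissue mixed into normal samples and of a piece of tissue from nearer the small intestine were chosen after the result was seen. Those of slide and of weaker signal were written before their own results were seen. The low Hox levels of mouse 107 that the latter addresses were themselves found after seeing the data.

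In 31 of 451 groups of 4 arrays, a gene or list had 1 array far from the other 3, the gap to the nearest being above Dixon's 95% critical value as a share of the group's range, and chance gives about 1 in 20 groups. Values are log2 levels relative to the array's 75th percentile, each followed by the gap as a share of the range. In wild-type normal tissue, the array of mouse 102 stood high for Il11 (−4.25, 0.8508) and Tnf (−3.06, 0.8712) and low for Cd177 (0.59, 0.8354) and Dut (−0.79, 0.8803). The array of mouse 105 stood high for Pfkm (1.21, 0.8575), the pyrimidine synthesis list (1.07, 0.9154) and the smooth muscle list (4.65, 0.9045), and low for the oxidative phosphorylation list (5.0, 0.8467). That of mouse 104 stood high for the ribosome biogenesis list (0.87, 0.9092), and that of mouse 108 low for Wif1 (−3.59, 0.8798) and the fibroblast and matrix list (1.72, 0.8568).

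In Apc normal tissue, the array of mouse 103 stood low for Fabp4 (0.50, 0.877), Sp5 (−5.89, 0.9526, not well above background there) and Slc16a3 (1.10, 0.8618). The array of mouse 106 stood high for Spp1 (−6.99, 0.8459) and Cxcr2 (−5.78, 0.8845), neither well above background on any Apc normal array, and for the fibroblast and matrix list (2.90, 0.8922), that of mouse 107 high for Cyp2c55 (6.86, 0.8325) and Pparg (3.96, 0.9086), and that of mouse 110 low for Clca1 (7.47, 0.8715). In polyps, the array of mouse 103 stood low for S100a8 (2.59, 0.8368), S100a9 (4.21, 0.8435), Bub1 (−0.79, 0.9211) and the neutrophil list (0.35, 0.8378). The array of mouse 106 stood low for Slc26a3 (−2.04, 0.8373) and Atoh1 (−0.61, 0.8526) and high for Gmps (−0.14, 0.8544), that of mouse 110 high for Paics (3.06, 0.8648) and Insl5 (0.98, 0.8296) and low for Mcm3 (2.55, 0.834), and that of mouse 107 high for Hoxa11 (−0.01, 0.8938).

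Of the 30 genes higher in Apc normal than in wild-type tissue, 6 would need under 10% of polyp tissue in the Apc normal samples to reach their level, among them Wif1 (2.02%), Mmp7 (1.18% to 1.21%), Sp5 (1.06% to 1.98%) and Habp2 (0.369% to 0.838%). The ranges set a wild-type level not above background at the background limit or at 0. The reference was genes outside the 30, more than 32-fold higher in polyps than in wild-type tissue and above background on all wild-type arrays. Of 47 such genes, 37 would rise 2-fold or more at 2.0% of polyp tissue, the upper end of the median share of the 6. These 37 stood at a median of −0.3112 from the level predicted (quartiles −0.80 and 0.53), so a small share of polyp tissue may account for the 6 genes. Of the 23 genes that would need 10% or more (Hbb-bt 62.5%, Alas2 50.3%), 12 would need over 100%. At the lowest share any of the 23 needs, 17.1% for Cxcl9, 47 such genes stood at a median of −2.575 from the level predicted (quartiles −3.41 and −1.94), which argues against polyp tissue as their source, and 1 gene was not higher in polyps. The 30 genes differed between slides 2 and 3 by a median of 0.3983 against 1.63 between the groups, but slide 1 held all wild-type arrays and no others, so slide and genotype cannot be told apart. A biological difference between the genotypes stays open and untested.

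The Apc normal array of mouse 107 was lower than the other 3 for Hoxd13 (−6.76 or lower), Hoxd11 (−4.11 or lower) and Hoxd12 (−3.41 or lower), not well above background there, and for Hoxb13 (−3.18), genes active toward the end of the body axis. Weaker signal of Hox probes on that array was argued against by 22 other Hox genes, whose median difference was 0.5216. Hox genes of paralog groups 10 to 13 minus those of groups 1 to 8 gave −3.704, and a candidate explanation, as a hypothesis from the same array, is a piece of tissue from nearer the small intestine, though 4 of the 9 genes of groups 10 to 13 were not clearly lower: Hoxa11 (1.76), Hoxa10 (0.46), Hoxc12 (0.12) and Hoxa13 (−0.05). The polyp array of that mouse, labelled as polyps in the plural, also had the lowest posterior Hox score of the polyp arrays (−1.69 against −0.50 to 0.89). Its Hoxa11 was the highest (−0.01 against −1.83 to −1.64), so a difference of the whole mouse stays open. The place each sample was taken from is not given in the sources used here. Without both arrays of that mouse 7580 genes differed between polyps and Apc normal tissue, and 31 between Apc normal and wild-type tissue, 13 of them among the 34.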

How the results depend on the processing

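The removal of mouse 107 and of the Apc normal arrays of mice 106 and 110 was chosen after the result was seen. For polyps against Apc normal tissue, the count of 9129 genes was 9321 with mouse number as a replicate block (pairing), 8915 with slide as a fixed block, 3466 on slide 2 and 1902 on slide 3 (fewer arrays), 4202 with a 2-fold minimum, and 7211 to 8682 without any single array. Of lists, 22 passed, 1 with an estimated correlation and 20 to 24 without any single array. For Apc normal against wild-type tissue, 34 genes passed. The count was 3 after normexp correction, 2 without the filter on dim probes, 14 with a variance trend and 171 with array weights. It was 226 with all 12 arrays in 1 fit (159 higher and 67 lower). It was 814 with slide as a random block in that fit, whose block correlation was negative, so 814 is no allowance for slide. The cause of the other changes of this count was not tested. Without any single array it ranged from 2 to 530: 9, 2, 2 and 11 without the wild-type array of mouse 102, 104, 105 and 108, 530 without the Apc normal array of mouse 103, and 2 without that of 106 or 110. It was 0 in limma without both of these Apc normal arrays. Lists numbered 15, 0 with an estimated correlation, 9 to 18 without any single array (9 without the Apc normal array of mouse 110) and 6 without both arrays. Without both, the direction of the list test turned for ribosome biogenesis, whose median stayed above 0 (0.01367, adjusted p = 0.920), and for macrophages (−0.07652, adjusted p = 0.870), with adjusted p from 0.00344 to 0.920 and 0.00175 to 0.870 over their alternatives, and the cause was not tested. For polyps against wild-type tissue, 12096 genes passed, 5144 with a 2-fold minimum and 10944 to 11804 without any single array. Lists numbered 22, 0 with an estimated correlation and 21 to 24 without any single array. Of results for single named genes and lists under the alternatives, 2166 and 929 kept direction and side of the threshold for polyps against Apc normal tissue, and 148 lost and 35 gained a call. For Apc normal against wild-type tissue 788 and 771 kept them, 188 lost and 25 gained a call. For polyps against wild-type tissue 1229 and 761 kept them, 29 lost and 8 gained a call. Genes well above background on no array of a group have bounds only, 331, 5 and 459 of the called genes in the 3 comparisons.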

Other observations

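The family screen and all tests of the mitochondrial lists were chosen after the result was seen, and the counts over splits of the arrays before.

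Gene families that share a symbol stem were screened in polyps against Apc normal tissue (424 families of 6 or more tested members, 41 past the preset test and 0 with an estimated correlation). Of 15 clustered protocadherins of the Pcdhb family 12 rose, such as Pcdhb18 (2.07 ± 0.15). Their median was 1.93, or 1.06 to 1.94 under 4 other scalings. All 6 interferon-induced membrane proteins of the Ifitm family rose, among them Ifitm3 (2.65 ± 0.30), as did 17 of 20 nuclear pore genes of the Nup family (Nup155 1.17 ± 0.10). Of 14 Wnt ligand genes 9 rose and 0 fell (preset adjusted p = 0.0485), among them Wnt5a (2.09 ± 0.23) and Wnt6 (4.89 ± 0.71). Of 16 matrix metalloproteinase genes 9 rose and 2 fell, with Mmp14 at 1.95 ± 0.16.

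Of 36 Cyp2 cytochromes 24 fell, such as Cyp2c29 (−3.81 ± 0.36) and Cyp2d22 (−3.57 ± 0.29), and 3 rose. Their median was −2.83, or −2.82 to −1.92 under 4 other scalings. Of 12 carboxylesterases 10 fell and 1 rose, with Ces2a at −4.13 ± 0.26. Of 9 sodium-coupled Slc5 transporters 7 fell, among them the short-chain fatty acid transporter Slc5a8 (−3.14 ± 0.25), and of 11 carbonic anhydrases 7 fell (Car2 −2.82 ± 0.22). Of 17 kallikreins 12 fell and 1 rose (Klk1 −2.36 ± 0.19). Of 52 ribosomal proteins of the Rpl family 19 fell, but their median of −0.26 changed sign under 2 of 4 other scalings (−0.25 to 0.09). The medians of the other families named here kept their sign under all 4, and adjusted p was 0.70 to 0.82 with an estimated correlation for these families.

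The 62 genes of the TCA cycle, oxidative phosphorylation and fatty acid oxidation lists differed by a mean of −0.86 between polyps and Apc normal tissue, beside −3.61 for smooth muscle markers. A smaller share of smooth muscle would need 48.8% of their signal to come from muscle, and then predicts −0.21 between Apc normal and wild-type tissue against −0.05 observed, a difference of 0.1544 (1.64 SE) that leaves it open. Over the 8 normal arrays the mitochondrial score correlated with the score of absorptive colonocytes (r = 0.885, two-sided exact permutation p = 0.00394, adjusted 0.00789 over 2 relations, rho = 0.833, exact permutation p = 0.0154), with r = 0.776 without the 2 arrays farthest from the median. For smooth muscle r was 0.317 (exact permutation p = 0.445, rho = 0.286), and within wild-type and Apc normal arrays, 4 each and too few for a test, the colonocyte r was 0.459 and 0.953. A smaller share of absorptive colonocytes in polyps is therefore a candidate explanation, as a hypothesis, and a change within the polyp cells stays open and untested.

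Each comparison was repeated over the 35 splits of its 8 arrays into 4 and 4. For polyps against Apc normal tissue 1 of 35, the real one, gave as many genes (9129, highest other 0). It was 1 for Apc normal against wild-type tissue (34, highest other 12) and 1 for polyps against wild-type tissue (12096, highest other 0). For the comparisons with wild-type tissue, whose groups share no mice, this is the smallest share that 35 splits can give. It argues against a chance split of the 8 arrays. The real split also parted the slide of the wild-type arrays from the others, so group and slide cannot be told apart. The count of 34 covers the 8 arrays together, and it fell to 2 without single arrays and to 0 without 2. Polyps and Apc normal tissue came from the same mice, so the 35 splits cannot exclude chance for the count of 9129. Only 8 splits part all 4 mice of that comparison, too few for a share under 0.05, and the highest other of them gave 0 genes and 25 lists. For lists past the preset test, 4 of 35 splits gave as many in the first comparison (22, highest other 25). It was 6 in the second (15, highest other 19) and 6 in the third (22, highest other 23). Apart from the real ones, these splits swapped 1 array between the groups and so kept most of the real grouping. The exception was the split with 19 lists in the second, which swapped 2. Splits with 2 arrays of each group on either side gave 0 to 12 lists in the first comparison. They gave 3 to 19 in the second and 1 to 9 in the third. The preset test therefore passed lists where the groups were balanced, and the splits do not exclude chance for the list counts.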
